A study of Homo sapiens with 4 samples.

How the data were processed

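RNA of 4 libraries of ACHN, a human renal cell carcinoma cell line, was measured by sequencing. There were 2 libraries of control cells and 2 libraries of ZCCHC8 knockout cells. Per the labels' protocols, RNA came from total cell lysates, ribosomal RNA was removed with a depletion kit, and libraries were made with a directional kit that marks the strand. Whether the strand was used when fragments were assigned to genes is not given in the sources used here, so values of a gene and of a transcript on its opposite strand can share fragments. The labels name no batch, and nothing in them says that libraries of one group came from separate cultures or clones. The p-values then measure only the spread between these libraries, which may be technical.

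The submitters' processing notes name cutadapt 1.9.3, HISAT2 2.0.4, Cuffdiff 2.2.1 and Cufflinks without a version, and the human genome build hg19. The roles and options of these tools and the gene annotation are not given in the sources used here. Coordinates are those of the deposited tables, on hg19, and mark the locus to which a table assigns a gene, which several overlapping genes can share. No genome sequence was used.

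One deposited table lists 20307 protein-coding entries and the other lists lncRNA transcripts. Each holds, per library, FPKM values made by the authors (fragments normalised to transcript length and library total, per the file headers) and a column that the file headers call counts. The deposited count columns are estimated counts (expected counts) multiplied by 1 factor per library. Low values of a library were spaced by a single step, which was the same in both tables and equalled 0.8799 and 1.1543 in control replicates 1 and 2 and 1.0437 and 0.9624 in knockout replicates 1 and 2. Divided by its step, 87.4% to 88.4% of coding values per library and 53.5% to 56.5% of lncRNA values above 0 came out within 0.01 of a whole number. The quotients, called fragments here, were rounded to whole numbers before the count test.

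The lncRNA table has 97286 lines because a transcript is repeated for each associated coding gene. The 59602 repeats were removed after a check that 0 of them held differing values, which left 37684 transcripts. Entries with the same symbol were summed within a table, giving 20232 coding symbols, of which 74 had more than 1 entry, and 23679 lncRNA symbols. Of these, 17847 coding symbols (88.2%) and 4924 lncRNA symbols (20.8%) matched a reference list of gene names. Symbols are printed as the tables give them. The number of per-sample value columns that could not be mapped to a library was 0.

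Fragments per library summed over both tables to 12024404 and 9166528 in control replicates 1 and 2 and to 10127589 and 10997893 in knockout replicates 1 and 2. A deeper library gives less counting error. At a count of 0, the limit used for folds was 3 fragments over a group, which covers counting error only, since the fragments carry no molecular identifiers.

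The design fixed before the data were examined named limma on log2(FPKM + pseudocount) as the main test, with edgeR in its place should the files hold raw counts. The deposited columns are scaled estimated counts, so that condition was not strictly met and the switch to edgeR departed from the design. Because fragments could be recovered, edgeR's quasi-likelihood test (glmQLFit and glmQLFTest, edgeR 4.0.16 in R 4.3.3) on the rounded estimated fragments was used, and limma 3.58.1 on log2(FPKM + 1) for coding genes and log2(FPKM + 0.5) for lncRNAs became an alternative. Libraries were scaled with 1 set of TMM factors computed over the tested genes of both tables (1.008, 1.013, 0.981 and 0.998). Coding genes with a mean FPKM of at least 1 over the 4 libraries and lncRNA genes with a mean FPKM of at least 0.5 were tested, each table on its own. A gene was called at a Benjamini-Hochberg adjusted p of at most 0.05. Log2 fold changes are knockout over control, with a standard error (SE) equal to the absolute log2 fold change divided by the square root of edgeR's F statistic. CPM are TMM-scaled fragments relative to the library total of both tables, given as mean ± SD of 2 libraries. An exact permutation test of 2 libraries against 2 cannot give a two-sided p below 0.333, so none was used.

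Gene lists were fixed before the data were examined: 30 for the coding table and 6 for the lncRNA table, tested with limma's camera at a preset inter-gene correlation of 0.01 where at least 3 members were tested. Camera compares a list with the other genes of its table. It was also run with a correlation estimated from the residuals of these 4 libraries. Fry tests whether the genes of a list move, on balance, one way. The classes of lncRNA are those of the deposited table, which does not define them, and were tested in the same way, and Fisher's exact test compared called with not called genes per class. KEGG pathways and Gene Ontology cellular components, as listed in the coding table, were tested with camera where 10 to 300 members were tested.

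Genes are named by a rule written before the data were examined. For coding genes it takes the NEXT members, the 7 largest rises and 7 largest falls among called genes with no overlap between the groups, and up to 3 members with the smallest p of each list with a called member or a camera call. For lncRNAs it takes the called genes and then those with the smallest p, 5 per direction, with named genes first. A few genes that the rule takes are left out of the text and still count in the list totals. Genes named outside this rule are said to have been chosen after their values were seen.

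The steps were tested on simulated counts drawn from the means, spread and depths of these libraries. Among 11649 coding genes, edgeR's test recovered 52.2% of genes changed 1.5-fold, 84.8% at 2-fold and 96.9% at 4-fold. Of its 226 calls 33 were false (14.6%, above the 5% aimed at), while 5% of unchanged genes had an unadjusted p under 0.05. DESeq2 1.42.0 recovered 43.3%, 74.2% and 95.4%, with 8 false among 184 calls (4.3%), and limma on FPKM 34.3%, 69.7% and 95.4%, with 8 false among 177 calls (4.5%). The simulated FPKM were the simulated counts scaled by library and by 1 factor per gene. They lack any further spread of the authors' FPKM, so limma's figures need not hold for the deposited values. On those, limma on log2(FPKM + 1) called 59 coding genes and DESeq2 908. Among 3304 lncRNA genes, whose replicates spread more, edgeR and limma recovered 0% of the changed genes at each of these fold sizes and DESeq2 0%, 0% and 3.4%, with 5 false among its 7 calls (71.4%), so single lncRNAs could hardly be called with 2 libraries per group. A simulated list of 50 coding genes raised 2-fold was found by camera with the preset (p = 4.42e-124) and the estimated correlation (p = 0.00117). Its genes were drawn independently, so this does not show how camera performs on correlated genes or smaller changes.

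Alternatives were other filters, scalings (median-ratio, TMM within each table, the authors' factors), entries not summed per symbol, the replicate number as a block, each library left out, the limma versions, DESeq2, edgeR's older quasi-likelihood method and the estimated correlation. The levels of sex-linked transcripts are not reported.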

Results

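RNA was sequenced from ACHN cells, a human line derived from a renal cell carcinoma, to ask how transcript levels change when the nuclear exosome targeting (NEXT) complex loses a subunit. NEXT hands short and unprocessed nuclear transcripts to the RNA exosome for decay and consists of the scaffold ZCCHC8, the RNA-binding protein RBM7 and the helicase MTR4, listed here under its older symbol SKIV2L2. The series title links NEXT to H3K27me3, the repressive histone mark laid down by Polycomb repressive complex 2 (PRC2), and to tumour progression. There were 2 libraries of control cells and 2 of ZCCHC8 knockout cells. Protein-coding entries held 10912604 and 8321161 fragments in control replicates 1 and 2 and 9076248 and 9901201 in knockout replicates 1 and 2. The lncRNA entries of these libraries held 1111809, 845372, 1051334 and 1096696 fragments. Replicates differed by more than sampling noise in each group, with a chi-square per degree of freedom of 5.71 in controls and 5.62 in knockouts over coding genes.

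ZCCHC8 mRNA was lower in both knockout libraries than in both controls. Its level fell from 80.1 ± 6.98 CPM in controls to 44.2 ± 1.69 CPM in knockouts (SD, 2 libraries each), from 1031 and 698 fragments to 427 and 498. The log2 fold change was −0.86 ± 0.10 (SE, adjusted p = 2.62e-04, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). ZCCHC8 lies on chromosome 12, 122957417 to 122985518 (hg19). The other NEXT subunits gave values close to those of controls. RBM7 measured 46.2 ± 0.99 CPM in controls and 45.6 ± 4.97 CPM in knockouts, and SKIV2L2 111 ± 5.28 and 113 ± 4.72 CPM. Their log2 fold changes were −0.02 ± 0.11 (adjusted p = 0.955) and 0.02 ± 0.08 (adjusted p = 0.898). With limma on log2(FPKM + 1) the ZCCHC8 change was −0.58 and did not pass (adjusted p = 0.136).

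**Figure D1:**
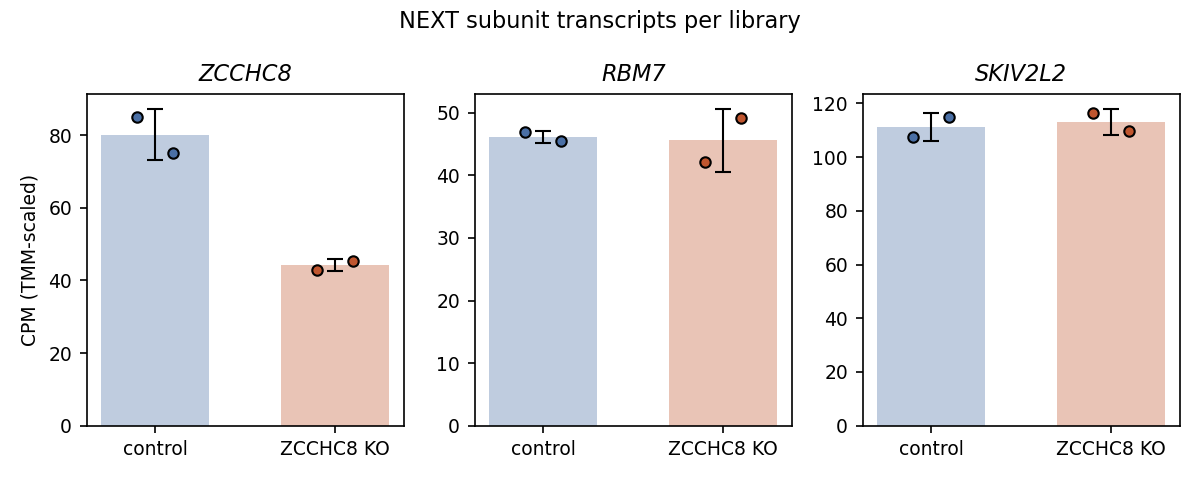
TMM-scaled CPM of the NEXT subunit transcripts ZCCHC8, RBM7 and SKIV2L2 in control and ZCCHC8 knockout libraries. Points are libraries, bars their mean and error bars the SD of 2 libraries. ZCCHC8 falls from a mean of 80.1 to 44.2 CPM, while RBM7 (46.2 and 45.6 CPM) and SKIV2L2 (111 and 113 CPM) have close means.

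ZCCHC8 knockout went with changed levels of 1198 of the 11733 coding genes tested, of which 518 rose and 680 fell. At a change of at least 2-fold there were 117 rises and 104 falls, and the median absolute log2 fold change of the called genes was 0.51. Among the largest falls, POU3F3 and EN2 encode neural transcription factors. POU3F3 dropped from 37.2 ± 10.8 to 1.63 ± 0.25 CPM (log2 fold change −4.53 ± 0.31, adjusted p = 1.43e-05). EN2 dropped from 8.86 ± 0.65 to 0.29 ± 0.02 CPM (−4.90 ± 0.51, adjusted p = 1.22e-04). SCIN, which encodes the actin-severing protein scinderin, fell from 85.3 ± 11.1 to 5.60 ± 1.09 CPM (−3.92 ± 0.17, adjusted p = 1.15e-07). SKAP1, which encodes an adaptor protein of T cell signalling, fell from 64 and 37 fragments in controls to 0 in both knockouts, at least 32.3-fold lower (adjusted p = 0.00117). FAM86B1, a member of a family of near-identical copies whose values are uncertain, had a log2 fold change of −4.04 ± 0.76 (adjusted p = 0.00441). Many of the named coding genes that fell lie on chromosome 7. They include EN2, SCIN, EZH2, KMT2C, HOXA3, MCM7, ASNS, PDIA4, INSIG1, CYP51A1, NDUFA4, MET, INTS1 and CPSF4. The called genes INHBA and IL6 on this chromosome rose. Genes, lists and pathways were not tested by chromosome, so whether these falls go with location or with gene function stays open.

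The largest rises were in transcripts with few fragments. MME, which encodes the kidney brush border peptidase neprilysin, rose from 0 and 10 to 87 and 74 fragments (log2 fold change 4.01 ± 0.63, adjusted p = 0.00156). It was not called by DESeq2 (adjusted p = 0.367), and without control replicate 2 the fitted value was 9.41, against a lone control at 0 fragments, which is no bound. POPDC3 rose from 0 and 2 to 56 and 33 fragments (5.34 ± 0.93, adjusted p = 0.00217; fitted value 8.56 without control replicate 2) and SAA1, an acute phase protein gene, from 1 and 1 to 35 and 21 (4.68 ± 0.90, adjusted p = 0.00425). CSGALNACT1, an enzyme gene of chondroitin sulfate synthesis, rose by 3.87 ± 1.13 (adjusted p = 0.0432) and SERF1B, which has a near-identical copy, by 3.89 ± 0.92 (adjusted p = 0.0155). The clone-named entries RP11-618P17.4 and CTD-3105H18.16 share their loci with other genes, so their values are uncertain. They were at 0 in both controls and at least 14-fold and at least 10-fold higher in knockouts (adjusted p = 0.0103 and 0.0292). Without control replicate 1 these rises, MME apart, were not called. The highest adjusted p with a library left out was 0.134 for RP11-618P17.4, 0.247 for CTD-3105H18.16, 0.0629 for POPDC3, 0.134 for SAA1, 0.207 for SERF1B and 0.378 for CSGALNACT1. Of these, RP11-618P17.4, CTD-3105H18.16, SERF1B and CSGALNACT1 also lost their calls without control replicate 2, CTD-3105H18.16 without knockout replicate 1, and SERF1B and CSGALNACT1 (2.55) without knockout replicate 2.

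The histone genes HIST2H2AA4 and HIST2H3A stood among the largest falls through 1 library. HIST2H2AA4 had 2.81 and 319 CPM in control replicates 1 and 2 and 1.01 and 1.46 CPM in the knockouts, and HIST2H3A had 1.32, 162, 0.60 and 0.91 CPM. Both lie in a duplicated stretch of chromosome 1 (149822643 to 149823191 and 149824181 to 149832714). The sister copy HIST2H2AA3 reached 73.7 CPM in knockout replicate 2 against 3.32 to 4.31 CPM in the other libraries. Without control replicate 2, the log2 fold changes were −1.17 for HIST2H2AA4 and −0.78 for HIST2H3A and neither was called. Both calls were also lost without knockout replicate 1, and that of HIST2H3A without knockout replicate 2 (adjusted p up to 0.368 and 0.710).

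Of the 1198 called genes, 1195 had no overlap between the groups, as had 54% of all tested genes, where chance gives 33.3%. The unadjusted p was under 0.05 for 2852 genes and the biological coefficient of variation was 0.099. The number of called genes was 412 without control replicate 1, 947 without control replicate 2, 907 without knockout replicate 1 and 1151 without knockout replicate 2. DESeq2 called 908 genes, 903 of them shared, and limma on log2(FPKM + 1), the test named in advance for FPKM values, called 59, of which 56 were shared. DESeq2 lost the calls of 12 of the 69 called genes that the naming rule takes, among them MME, CSGALNACT1, HIST1H2AC, EZH2, OAS3, CCNB1, RPS24, MT-CO1, MT-ATP8 and NDUFA4, and limma on log2(FPKM + 1) kept 11.

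**Figure D2:**
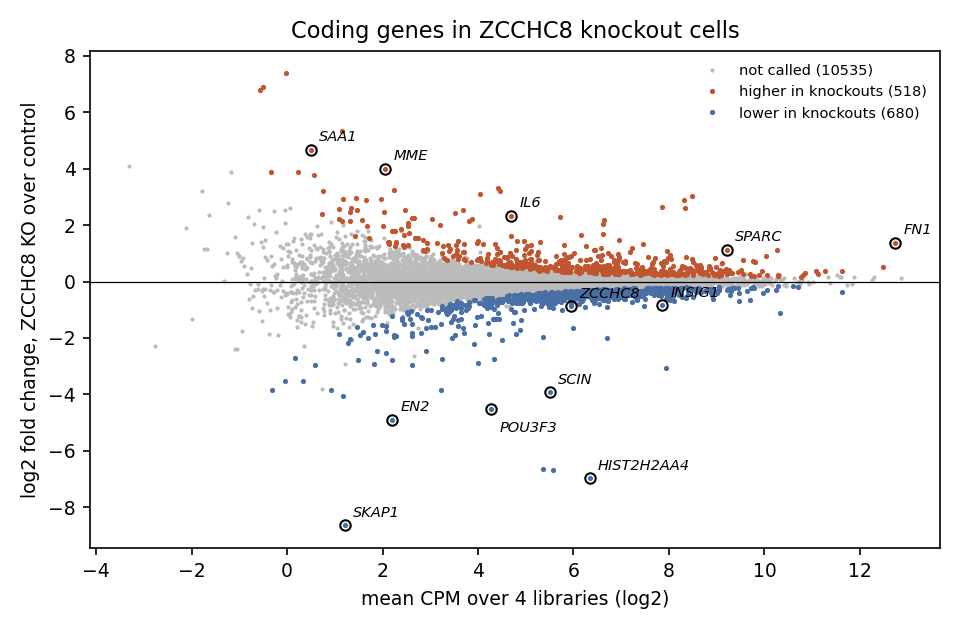
Log2 fold change of ZCCHC8 knockout over control against mean CPM (log2 axis) for the 11733 coding genes tested, each point a gene. The 518 called genes that rose are in orange, the 680 that fell in blue and the rest in grey; the circled points are named in the text, with POU3F3, EN2, SCIN and SKAP1 far below 0.

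Most called genes of epithelial-mesenchymal transition rose. Of 23 tested members of the epithelial-mesenchymal list, 14 rose, 3 fell and the rest were not called, with the same 14 and 3 adjusted over the list alone. FN1, the fibronectin gene, rose from 3808 ± 940 to 9863 ± 135 CPM (log2 fold change 1.37 ± 0.11, adjusted p = 4.93e-05). The thrombospondin gene THBS1 rose from 4694 ± 315 to 6729 ± 13.9 CPM (0.52 ± 0.05, adjusted p = 6.37e-05). SPARC, the osteonectin gene, rose from 374 ± 80.1 to 816 ± 7.73 CPM (1.13 ± 0.10, adjusted p = 6.37e-05). Other members that rose, chosen after their values were seen, included COL1A1 (collagen I, 3.11 ± 0.36), SNAI2 (2.95 ± 0.55) and TAGLN (2.21 ± 0.25). SNAI2 encodes a transcription factor and TAGLN an actin-binding protein. The 3 that fell, likewise chosen afterwards, were TNC (tenascin C, −1.07 ± 0.16), ACTA2 (smooth muscle actin, −0.54 ± 0.13) and VIM (vimentin, −0.16 ± 0.05). Without control replicate 1, SNAI2, ACTA2 and VIM were not called (adjusted p up to 0.103, 0.167 and 0.27), nor were ACTA2 and VIM without control replicate 2 or knockout replicate 1, or VIM without knockout replicate 2. The list's median log2 fold change was 0.51 and camera's adjusted p 6.5e-14 (adjusted p = 0.55 with an estimated correlation; fry adjusted p = 0.0766).

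Called genes of TGF-beta and BMP signalling rose. Of 14 targets and components tested, 7 rose and 0 fell (8 and 1 adjusted over the list alone), with a median of 0.52. INHBA, the activin A subunit gene, rose from 149 ± 13.9 to 267 ± 0.24 CPM (0.85 ± 0.07, adjusted p = 4.93e-05), and the ligand gene TGFB2 (0.78 ± 0.12, adjusted p = 0.00177) and the TGF-beta target PMEPA1 (0.81 ± 0.13, adjusted p = 0.00180) also rose. Camera's adjusted p was 3.84e-06 (adjusted p = 0.55 with an estimated correlation; fry adjusted p = 0.0766), and the median was 0.31 to 0.35 under the limma versions. Control replicate 2 lay between control replicate 1 and the knockouts for these genes, at a median 20.9% of the way for the 17 called epithelial-mesenchymal members and 15.3% for the 7 called TGF-beta members (95% bootstrap interval −6.5% to 37.2%). In control replicates 1 and 2, FN1 measured 3143 and 4472 CPM.

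Most called genes of cholesterol synthesis fell. Of 24 tested, 8 fell and 1 rose (11 and 1 adjusted over the list alone), with a median log2 fold change of −0.23. INSIG1, a sterol-responsive regulator of the pathway, fell from 299 ± 0.17 to 167 ± 1.16 CPM (−0.84 ± 0.06, adjusted p = 2.11e-05), and the enzyme genes CYP51A1 (−0.64 ± 0.08, adjusted p = 3.62e-04) and MSMO1 (−0.55 ± 0.08, adjusted p = 9.35e-04) fell too. Camera's adjusted p for the list was 6.44e-07 (adjusted p = 0.554 with an estimated correlation; fry adjusted p = 0.0714). INSIG1 and CYP51A1 lie on chromosome 7, where many named genes outside this pathway also fell, and MSMO1 lies on chromosome 4. Whether the list stands out without its chromosome 7 members was not tested.

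The lists of histone, mitotic and p53 target genes also passed camera in the downward direction. Of 48 replication-dependent histone genes, 8 fell and 0 rose (10 and 0 adjusted over the list alone), with a median of −0.21. Among them were HIST1H1D (−0.33 ± 0.06, adjusted p = 0.0037), HIST1H4B (−0.48 ± 0.09, adjusted p = 0.00527) and HIST1H2AC (−0.37 ± 0.09, adjusted p = 0.022). The list's adjusted p by camera was 0.00345 (adjusted p = 0.55 with an estimated correlation; fry adjusted p = 0.0899). Of 30 genes of G2/M and mitosis, 3 fell and 0 rose, also adjusted over the list alone, with a median of −0.15. These were the mitotic kinase genes NEK2 (−0.53 ± 0.11) and BUB1 (−0.27 ± 0.07) and the cyclin gene CCNB1 (−0.26 ± 0.07). Camera gave the G2/M list an adjusted p of 0.00345 (adjusted p = 0.691 with an estimated correlation; fry adjusted p = 0.0899). Of 22 p53 targets, 3 fell and 0 rose, also adjusted over the list alone, with a median of −0.18. These were the cell cycle inhibitor gene CDKN1A (−0.43 ± 0.07), the death receptor gene FAS (−0.47 ± 0.10) and the nuclease gene AEN (−0.45 ± 0.10). Camera gave the p53 list an adjusted p of 0.0392 (adjusted p = 0.691 with an estimated correlation; fry adjusted p = 0.119).

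Of 29 genes of G1/S and DNA replication, 1 fell and 1 rose, also adjusted over the list alone (camera adjusted p = 0.740). The helicase subunit gene MCM7 fell (−0.39 ± 0.06, adjusted p = 0.00203), while MCM5 measured 0.29 ± 0.09 (adjusted p = 0.0683; 0.0443 without knockout replicate 2). Without control replicate 1, HIST1H2AC, NEK2, BUB1, CCNB1, FAS and AEN were not called, nor were HIST1H2AC, BUB1 and CCNB1 without control replicate 2 or knockout replicate 1 or CCNB1 without knockout replicate 2. The highest adjusted p with a library left out was 0.116, 0.113, 0.185, 0.219, 0.0682 and 0.138 for these genes in this order. The p53 list was not called without control replicate 1, control replicate 2 or knockout replicate 1 (adjusted p up to 0.219).

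**Figure D3:**
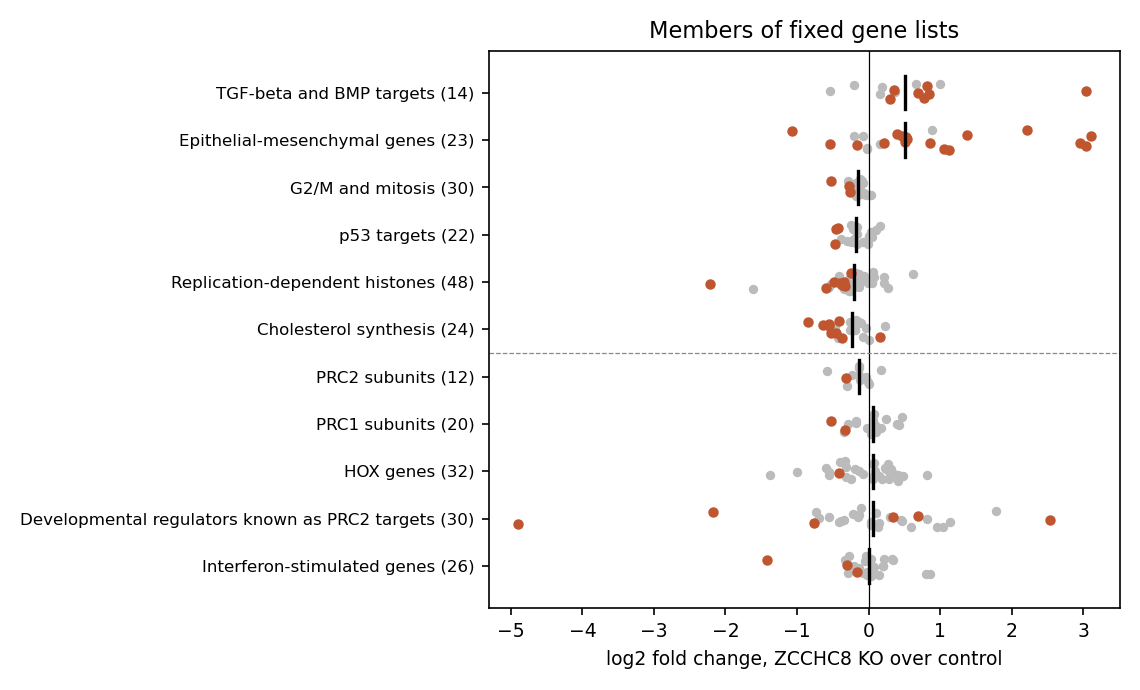
Log2 fold change of ZCCHC8 knockout over control for the tested members (number in brackets) of fixed gene lists, with called members in orange, the others in grey and the list median as a vertical bar. The 6 lists above the dashed line passed camera at the preset correlation, from TGF-beta and BMP targets (median 0.52) to cholesterol synthesis (median −0.23); the Polycomb, HOX, developmental and interferon lists below it did not.

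Some transcripts of the Polycomb machinery were called, as were 1198 of the 11733 coding genes tested. Of 12 PRC2 subunit genes, the methyltransferase gene EZH2 fell (94 ± 5.54 to 75.6 ± 6.27 CPM, −0.31 ± 0.09, adjusted p = 0.0483) and 0 rose, with 0 called adjusted over the list alone, a list median of −0.13 and 2 members above 0. PHF1 (−0.58 ± 0.24, adjusted p = 0.158) and EED (−0.30 ± 0.13, adjusted p = 0.185) were not called. Of 20 PRC1 subunit genes, PHC2 (−0.52 ± 0.09, adjusted p = 0.00252) and PCGF5 (−0.33 ± 0.08, adjusted p = 0.0165) fell, 2 also adjusted over the list alone, and BCOR measured −0.34 ± 0.11 (adjusted p = 0.0649). Among 12 genes of H3K27 demethylases and opposing factors, the methyltransferase gene KMT2C fell (−0.26 ± 0.07, adjusted p = 0.0259; 1 also adjusted over the list alone), while limma on log2(FPKM + 1) gave 0.12 for KMT2C, not called. SETD2 (0.16 ± 0.07, adjusted p = 0.191) and SMARCA4 (0.15 ± 0.07, adjusted p = 0.217) were not called. EZH2 and KMT2C lie on chromosome 7, where genes outside these lists such as PDIA4 (−0.37 ± 0.06) and MCM7 (−0.39 ± 0.06) also fell, though INHBA and IL6 rose. Their falls are therefore not particular to Polycomb genes. By camera the adjusted p was 0.321 for PRC2, 0.983 for PRC1 and 0.983 for the opposing factors. EZH2 also lost its call with no filter, at 5 FPKM or more, with median-ratio scaling, TMM within the coding table, filterByExpr and DESeq2 (adjusted p from 0.0518 to 0.111). Without control replicate 1, EZH2, PCGF5 and KMT2C were not called (adjusted p up to 0.228, 0.110 and 0.261). Without control replicate 2, EZH2 and PCGF5 also lost their calls, as did PCGF5 without knockout replicate 1 and EZH2 and KMT2C without knockout replicate 2.

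Tested genes known as PRC2 targets in development went both ways. Of 86 listed genes 30 were tested, so targets below the expression threshold in these cells were not examined. Of the 30 tested, 3 rose and 3 fell (5 and 4 adjusted over the list alone), with a median of 0.06. EN2 fell as given above and the nuclear receptor gene NR2F2 fell from 109 ± 5.05 to 64.2 ± 7.58 CPM (−0.76 ± 0.10, adjusted p = 4.17e-04), while PAX8, a renal lineage transcription factor, rose from 490 ± 9.58 to 619 ± 9.27 CPM (0.34 ± 0.05, adjusted p = 0.00149). The remaining called members, named after their values were seen, were IRX5, which fell (−2.18 ± 0.55), and BMP4 (2.54 ± 0.57) and the cell cycle inhibitor CDKN2B (0.69 ± 0.15), which rose. These 3 were not called without control replicate 1 (adjusted p up to 0.112, 0.232 and 0.208), nor was IRX5 without control replicate 2 or knockout replicate 1. Of 32 HOX genes, HOXA3 fell (−0.41 ± 0.10, adjusted p = 0.022; 1 also adjusted over the list alone), while HOXA9 (−0.31 ± 0.10, adjusted p = 0.0617; 0.0316 without knockout replicate 1) and HOXA6 (−1.38 ± 0.44, adjusted p = 0.0681) were not called. HOXA3 and HOXA6 share 1 locus in the table, so their values are uncertain, and HOXA3 was not called without control replicate 1, control replicate 2 or knockout replicate 2 (adjusted p up to 0.138). Camera gave 0.981 as the adjusted p for the developmental list and 0.983 for HOX genes. EN2 and the HOXA genes named here lie on chromosome 7, as do many of the other named genes that fell.

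Called epithelial and renal genes went both ways. Of 14 epithelial junction genes, 5 fell and 2 rose (5 and 3 adjusted over the list alone; camera adjusted p = 0.699). Keratin 18 (KRT18) fell from 540 ± 18.9 to 403 ± 6.99 CPM (−0.42 ± 0.06, adjusted p = 5.05e-04) and E-cadherin (CDH1) from 59.9 ± 1.33 to 40.6 ± 3.67 CPM (−0.56 ± 0.11, adjusted p = 0.00507). The tight junction gene TJP1 rose (0.32 ± 0.06, adjusted p = 0.00504; 0.0726 without control replicate 1). Of 10 renal tubule markers, 2 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.360). The receptor gene MET fell from 1013 ± 54.7 to 648 ± 37.1 CPM (−0.65 ± 0.06, adjusted p = 6.37e-05), and GATM, named after its value was seen, fell by 0.93 ± 0.22 on the log2 scale. GATM measured −1.16 to −0.75 with 1 library left out, but was not called without control replicate 1, control replicate 2 or knockout replicate 1. PAX8 and MME, given above, rose. As markers of other cell types, 3 fibroblast genes were tested and 0 called over all genes (1 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.983). For leukocytes 2 genes (CD68 and CD74) were tested and 0 called, and 0 endothelial markers reached the expression threshold.

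Some interferon, stress and cytokine genes were called, while none of their lists passed camera. Of 26 interferon-stimulated genes, 3 fell and 0 rose, also adjusted over the list alone (camera adjusted p = 0.983). They included IFI44L (15.6 ± 0.77 to 5.89 ± 1.63 CPM, −1.42 ± 0.24, adjusted p = 0.0028) and OAS3 (−0.30 ± 0.08, adjusted p = 0.0356). Of 18 NF-kB and cytokine genes, 1 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.333). IL6 rose from 8.85 ± 4.70 to 42.9 ± 3.97 CPM (2.33 ± 0.24, adjusted p = 1.19e-04), while VCAM1 (−0.71 ± 0.24, adjusted p = 0.0838; 0.0162 without knockout replicate 2) and NFKBIA (0.33 ± 0.12, adjusted p = 0.125) were not called. Of 25 genes of the unfolded protein and integrated stress responses, 4 fell and 1 rose, also adjusted over the list alone (camera adjusted p = 0.321). Those that fell included asparagine synthetase ASNS (−0.77 ± 0.11), the chaperone gene PDIA4 (−0.37 ± 0.06) and PSAT1 (−0.30 ± 0.07). Of 25 hypoxia and glycolysis genes, 3 rose and 3 fell (4 and 5 adjusted over the list alone; camera adjusted p = 0.981), including the glucose transporter gene SLC2A1 (0.58 ± 0.10), VEGFA (0.51 ± 0.11) and ALDOA (−0.32 ± 0.06). Of 23 immediate early genes, DUSP1 rose (0.47 ± 0.10) and FOS fell (−1.06 ± 0.23), 1 and 1 also adjusted over the list alone, and IER3 measured 0.39 ± 0.12 (adjusted p = 0.0706; camera adjusted p = 0.981 for the list). The genes OAS3, PSAT1, SLC2A1, VEGFA, DUSP1 and FOS were not called without control replicate 1. Their highest adjusted p with a library left out was 0.277, 0.1, 0.0555, 0.104, 0.132 and 0.0666. OAS3 and FOS also lost their calls without control replicate 2, and OAS3, PSAT1 and VEGFA without knockout replicate 1.

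Some ribosomal, respiratory and RNA-processing genes were called, and none of these lists passed camera. Of 78 ribosomal protein genes, RPL23 (0.23 ± 0.06, adjusted p = 0.0242) and RPS24 (0.35 ± 0.10, adjusted p = 0.0383) rose, with 0 called adjusted over the list alone (camera adjusted p = 0.299). RPL18 measured −0.21 ± 0.06 (adjusted p = 0.0583). Of 44 nuclear-encoded genes of oxidative phosphorylation, 5 fell and 0 rose, also adjusted over the list alone (camera adjusted p = 0.321). They included UQCRC2 (−0.37 ± 0.07), ATP5B (−0.23 ± 0.05) and NDUFA4 (−0.33 ± 0.09). Of 12 mitochondrially encoded genes, 2 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.321). MT-ND6 rose (0.43 ± 0.05, adjusted p = 2.95e-04) and MT-CO1 fell (−0.39 ± 0.08, adjusted p = 0.00985). MT-ND6 is assigned to a locus that 18 genes share (7586 to 15953 of the mitochondrial genome), among them MT-ATP8 on the opposite strand. The value of MT-ND6 is therefore uncertain where strand was not used. MT-ATP8 measured 33.7, 0, 116 and 62.1 CPM in the 4 libraries and rose (adjusted p = 0.0379), but it overlaps MT-ATP6, its value is uncertain, and its call was lost without knockout replicate 1 (adjusted p up to 0.118).

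Of 15 nonsense-mediated decay factors 1 fell and 0 rose, with 0 called by edgeR adjusted over the list alone (camera adjusted p = 0.981). RNPS1 measured −0.17 ± 0.07 (adjusted p = 0.137) and UPF1 −0.18 ± 0.09 (adjusted p = 0.244). Of 28 Integrator and 3′ end processing genes, INTS1 (−0.37 ± 0.07, adjusted p = 0.00573) and CPSF4 (−0.61 ± 0.12, adjusted p = 0.00637) fell, 2 also adjusted over the list alone (camera adjusted p = 0.740). CPSF6 measured 0.17 ± 0.07 (adjusted p = 0.119). Of 14 RNA exosome genes and of 9 genes of the PAXT connection and the nuclear cap-binding complex 0 were called by edgeR, also adjusted over the list alone (camera adjusted p = 0.981 and 0.993). The 3 NEXT subunits as a list had a camera adjusted p of 0.290, with 1 called, also adjusted over the list alone. Without control replicate 1, RPL23, RPS24, MT-CO1, UQCRC2, ATP5B, NDUFA4, INTS1 and CPSF4 were not called. Their highest adjusted p with a library left out was 0.138, 0.264, 0.0638, 0.103, 0.0822, 0.193, 0.0852 and 0.0702. RPL23, RPS24, ATP5B and NDUFA4 also lost their calls without control replicate 2, RPL23, RPS24 (0.15) and NDUFA4 without knockout replicate 1, and ATP5B and NDUFA4 without knockout replicate 2, where RPS24 measured 0.53 and MT-CO1 −0.23.

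Fry's adjusted p among coding lists that camera did not call was 0.0714 for the unfolded protein and integrated stress responses, 0.0766 for the epithelial junction, oxidative phosphorylation and NEXT lists and 0.176 to 0.995 for the others. The median, the mean and the direction of camera differed in sign for several lists that were not called. They were the PAXT list (median 0.02, mean −0.06), HOX genes (0.07 and −0.05), epithelial junction genes (0.04 and −0.21), hypoxia genes (−0.01 and 0.05) and the fibroblast markers (−0.07 and 0.1). Interferon-stimulated genes had a median of 0.01 and a downward direction. Among lncRNAs, the HOX cluster and microRNA host lists had medians of 0.05 and 0.14 with a downward direction relative to other lncRNAs.

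Among lncRNAs, those that the table lists as bidirectional, a class it does not define, were higher in the knockouts as a class. Of 255 tested, 219 (85.9%) had a positive log2 fold change, with a median of 1.08, or 1.0 with the 13 genes at 0 in controls and the 1 at 0 in knockouts placed at their bounds. The class median relative to controls was 0.72 to 1.1 in the 4 pairs of a knockout and a control library, 0.30 between the controls and 0.01 between the knockouts. Summed over bidirectional lncRNAs with a mean of at most 10 CPM, the level was 264 and 332 CPM in the controls and 531 and 540 CPM in the knockouts. The whole class held 2.42% and 2.32% of fragments in controls and 2.62% and 2.35% in knockouts, most of it from the abundant RNAs RN7SK, RN7SL1 and RMRP, named after their values were seen, which the table also lists as bidirectional (0.05 ± 0.11, 0.10 and −0.10 ± 0.08). Camera's adjusted p was 4.87e-07 (adjusted p = 0.399 with an estimated correlation). Fry, which does not compare with other lncRNAs, did not single out this class. Its unadjusted p was 0.0418 for bidirectional lncRNAs, against 0.0205 for exon sense-overlapping and 0.0899 for intron sense-overlapping ones. All lncRNA medians depend on scaling. With TMM over both tables the median of all 3670 tested lncRNAs was 0.30, and with TMM over the lncRNA table alone it was 0.02. The bidirectional median was then 0.80, and 0.48 to 0.95 under the limma versions, in each of which the class was called.

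Antisense classes had medians above that of all lncRNAs but did not pass at the filter and scaling chosen. The median was 0.48 for 268 natural antisense genes (72.8% positive, camera adjusted p = 0.0669) and 0.73 for 171 intronic antisense genes (70.8% positive, adjusted p = 0.118), and under lncRNA-only scaling 0.20 and 0.45, where both classes were called (adjusted p = 0.0452 each). Both were also called at 1 FPKM or more, with filterByExpr and at 20 fragments or more (adjusted p from 0.00277 to 0.0367). With 1 library left out the medians were 0.48 to 0.85 for natural and 0.47 to 1.02 for intronic antisense genes, and under the limma versions 0.09 to 0.46 and 0.19 to 0.60. Summed over natural antisense genes with a mean of at most 10 CPM, levels were 322 and 363 CPM in controls and 530 and 509 CPM in knockouts, and the whole class held 0.115% and 0.123% of fragments in controls and 0.157% and 0.153% in knockouts. Fragments of an antisense transcript and of the gene opposite cannot be told apart where strand was not used. The 978 intergenic genes had a median of 0.27 (camera adjusted p = 0.827) and the 507 intron sense-overlapping genes 0.28 (adjusted p = 0.148), each −0.01 under lncRNA-only scaling. The 727 exon sense-overlapping genes had a median of 0.07 (−0.22 under lncRNA-only scaling) and stood below the other lncRNAs (adjusted p = 0.0271; adjusted p = 0.125 with an estimated correlation). In this class the median was positive and the test pointed down, since camera compares with the other lncRNAs. The call of the exon sense-overlapping class was lost without control replicate 1 or knockout replicate 2 (adjusted p up to 0.218), and the natural antisense class was called without control replicate 2 (median 0.85, adjusted p = 0.0424).

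**Figure D4:**
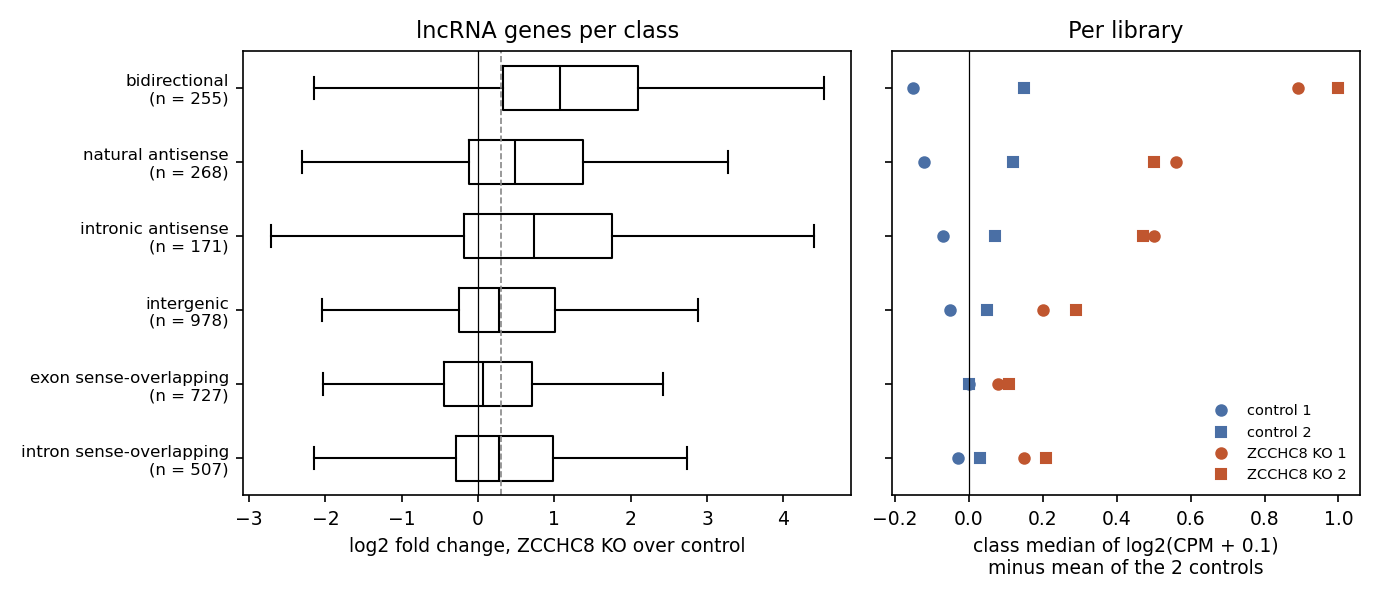
Left, log2 fold change of ZCCHC8 knockout over control for lncRNA genes of each class; boxes span the quartiles with the median as a line, whiskers reach to 1.5 times the quartile range, and the dashed line marks the median of all tested lncRNAs, 0.30. Right, class medians per library of log2(CPM + 0.1) minus the mean of the controls, with both knockout libraries to the right of both controls in each class and furthest for bidirectional lncRNAs.

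Single lncRNAs varied too much between replicates for most to be called. Their biological coefficient of variation was 0.569, 473 of 3670 had an unadjusted p under 0.05 (378 higher and 95 lower), and 1 was called by edgeR's test, against 64 (45 higher and 19 lower) by DESeq2, which in simulated lncRNA counts made 7 calls of which 5 were false, and 2 by limma on log2(FPKM + 0.5). The called transcript, XLOC_l2_007470, fell from 9.35 ± 0.04 to 0.10 ± 0.01 CPM (113, 87, 1 and 1 fragments; log2 fold change −6.44 ± 0.46, adjusted p = 0.0094). It overlaps an exon of a coding gene in sense and shares its locus (chromosome 2, 105469743 to 105542510) with POU3F3, which also fell. Its call was lost with any 1 library left out (adjusted p from 0.0549 to 0.431). Among bidirectional lncRNAs chosen after their values were seen because they were higher in knockouts, STAM-AS1 measured 1.02 ± 0.39 CPM in controls and 5.55 ± 0.02 CPM in knockouts (log2 fold change 2.47 ± 0.43), RAB30-AS1 7.05 ± 0.53 and 15.3 ± 0.28 CPM (2.16-fold) and SNHG18 2.72 ± 2.10 and 12.8 ± 0.99 CPM (2.29 ± 0.53). None passed, with adjusted p of 0.229, 0.246 and 0.269.

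The nuclear lncRNA MALAT1 measured 2603 ± 189 CPM in controls and 4021 ± 424 CPM in knockouts (0.63 ± 0.10, adjusted p = 0.203). NEAT1, the scaffold of paraspeckles, measured 1342 ± 216 and 2166 ± 157 CPM (0.69 ± 0.13, adjusted p = 0.233). KCNQ1OT1 (0.48 ± 0.10, adjusted p = 0.246) and TUG1 (0.28 ± 0.12, adjusted p = 0.397) gave positive values as well, but 0.19 and 0 under lncRNA-only scaling. Under that scaling MALAT1 and NEAT1 measured 0.34 and 0.41, and the 7SK RNA RN7SK and RMRP, given above, −0.24 and −0.39. These 6 were chosen after their values were seen. None of the 6 lncRNA lists passed camera, with adjusted p from 0.196 to 0.799 and 0 members called over all lncRNAs. The medians were 0.47 for 14 abundant nuclear lncRNAs (7 higher and 1 lower adjusted over the list alone) and 0.43 for 16 lncRNAs studied with PRC2 (3 and 1). They were 0.26 for 20 snoRNA host genes, 0.14 for 10 microRNA host genes and 0.05 for 13 HOX cluster lncRNAs, each with 0 called adjusted over the list alone. For 9 small nuclear, 7SK and RNA component genes (1 and 0) the median was 0.05, or 0.10 with a member at 0 placed at its bound. Fry, which does not compare with other lncRNAs, gave an adjusted p of 0.0382 for the snoRNA host, PRC2, nuclear and small nuclear lists, 0.709 for the HOX cluster and 0.201 for the microRNA hosts.

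Entries listed in the lncRNA table under the symbol of a coding gene made up the rest of the strongest values, none called. On the rising side IGFBP3 measured 33.2 ± 9.92 and 170 ± 17 CPM (2.36 ± 0.25, adjusted p = 0.148). ZBTB24, DYSF and BACE2 were at 0 in both controls and at least 166-fold, at least 78.9-fold and at least 89.5-fold higher in knockouts (adjusted p = 0.148, 0.148 and 0.156). GOLGA8A had 0, 0.11, 24.2 and 9.56 CPM (adjusted p = 0.156). On the falling side KCP measured −1.86 ± 0.26 (adjusted p = 0.156). TENC1 and RAB15 were at 0 in both knockouts, at least 40.1-fold and at least 32-fold lower (adjusted p = 0.156 and 0.185). ZNF138 had 3.96, 2.37, 0 and 0.18 CPM (adjusted p = 0.211). The coding and lncRNA entries of the same symbol, summed, lay close in both groups for 3 of these symbols. The sums were 36.9 ± 4.64 CPM in controls and 31.8 ± 4.72 CPM in knockouts for ZBTB24, 32.8 ± 2.45 and 34.6 ± 0.40 CPM for GOLGA8A and 42.0 ± 0.31 and 39.9 ± 2.2 CPM for RAB15. For 5 others the sum moved the same way as the lncRNA entry. It was 43.3 ± 24 CPM in controls and 186 ± 9.81 CPM in knockouts for IGFBP3, 92.5 ± 21.5 and 220 ± 9.53 CPM for DYSF and 109 ± 3.12 and 139 ± 2.36 CPM for BACE2. For TENC1 it was 21.5 ± 0.2 and 11.6 ± 0.35 CPM and for ZNF138 19.1 ± 1.06 and 14.3 ± 0.89 CPM.

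Control replicate 2 lay between control replicate 1 and the knockouts across unrelated genes. On linear CPM, it stood at a median 20.3% of the way to the knockouts for 40 abundant called genes that rose at least 2-fold (95% bootstrap interval 19% to 22.4%) and 19.6% for 23 that fell at least 2-fold (17.6% to 25.5%). Among abundant called genes with smaller changes it stood at 18.5% for 377 that rose and 18.5% for 530 that fell. ZCCHC8 itself was at 24.1% and the summed bidirectional lncRNAs at 25.1% (14.3% to 34.7%). The called members of the cholesterol list, at 2.8% (−12.6% to 36.9%), the histone list, at −8.1% (−30.4% to 45.4%), and the G2/M list, at −14.8% (−60.8% to 22.2%), had intervals that included 0. Without control replicate 2, 947 coding genes were called, of which 841 were shared with the full set.

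**Figure D5:**
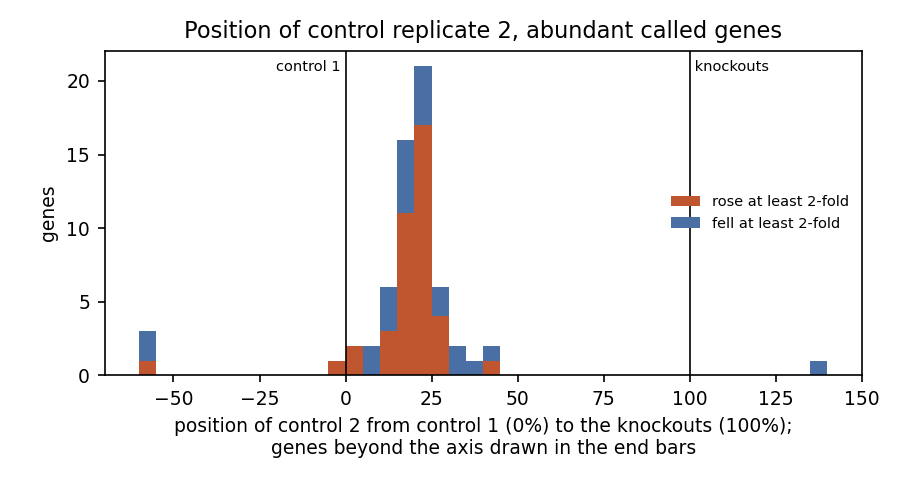
Position of control replicate 2 between control replicate 1 (0%) and the mean of the knockouts (100%) on linear CPM, for the abundant called genes (mean of at least 20 CPM) that changed at least 2-fold, 40 that rose in orange and 23 that fell in blue; genes beyond the axis are drawn in its end bars. Most genes gather near 20.3% and 19.6%, the medians of those that rose and fell.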

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

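The settings in this part chosen only after the data were seen were DESeq2, edgeR's older method, TMM within each table, the authors' factors, filterByExpr, a minimum of 20 fragments, leaving out sense-overlapping lncRNAs and the estimated correlation for lncRNA classes. Limma at pseudocounts of 1 for coding genes and 0.5 for lncRNAs was the test named before the data were examined, and became an alternative once fragments had been recovered. In simulated counts at these depths and this spread, edgeR and limma recovered 0% of changed lncRNAs and DESeq2 up to 3.4%; depth was not varied. With 1 library left out, the lone library of its group is assumed to vary like the other group. Whether libraries of a group came from separate cultures is not known. The cause was not tested for any change of call below.

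The number of coding genes called stayed within 1.5 times of 1198 with no filter (1191), at least 5 FPKM (1070), median-ratio scaling (1174), TMM within the table (1168, 49.7% of them higher against 43.2%), the authors' factors (1292, 35.5% higher), entries not summed (1193), filterByExpr (1218), DESeq2 (908) and edgeR's older method (1138). It was 412 to 1151 with 1 library left out. Limma called 59 at a pseudocount of 1, 3 at 0.1, 57 at 0.5, 57 after quantile normalisation (35 higher and 22 lower, 61.4% higher), 0 without a trend (by limma) and 56 with the robust version. The ZCCHC8 change under these 6 versions was −0.58, −0.60, −0.59, −0.53, −0.58 and −0.58 (adjusted p from 0.136 to 0.268), and −0.94 to −0.77 with 1 library left out (adjusted p up to 0.00433). For KMT2C they gave 0.12, 0.12, 0.12, 0.16, 0.12 and 0.12, opposite to edgeR, none called.

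The replicate numbers did not pair the libraries, with a correlation of same-number deviations of 0.08 in coding genes and 0.02 in lncRNAs. With the replicate number as a block 1215 coding genes were called (535 higher and 680 lower, 1142 shared), and 0 lncRNAs (XLOC_l2_007470 at an adjusted p of 0.0577). Of the 69 called coding genes named by the rule 68 kept their call under the block, EZH2 being the exception.

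Of the 6 called lists, the p53 list was not called at 5 FPKM (−0.15, adjusted p = 0.0628) or under limma at pseudocounts of 0.1 (−0.18, 0.0527) and 0.5 (−0.18, 0.0511) or after quantile normalisation (−0.12, 0.0869). With 1 library left out its median was −0.23 to −0.14 (adjusted p 0.0306 to 0.219). The G2/M list was not called under limma at pseudocounts of 1 (−0.14), 0.1 (−0.14) and 0.5 (−0.14), without a trend (−0.14), with the robust version (−0.14) or after quantile normalisation (−0.11), with adjusted p from 0.0614 to 0.134. With an estimated correlation 0 lists were called: histones −0.21 (adjusted p = 0.55), p53 −0.18 (0.691), G2/M −0.15 (0.691), epithelial-mesenchymal 0.51 (0.55), TGF-beta 0.52 (0.55) and cholesterol −0.23 (0.554). In the other settings run on them the epithelial-mesenchymal, TGF-beta, cholesterol and histone lists were called, at 0.45 to 0.56, 0.37 to 0.63, −0.36 to −0.25 and −0.26 to −0.16 with 1 library left out and 0.46 to 0.49, 0.31 to 0.35, −0.26 to −0.21 and −0.30 to −0.27 under the limma versions.

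Bidirectional lncRNAs were called by camera in all settings run on them (0.91 to 1.33 with 1 library left out, 0.48 to 0.95 under the limma versions) except the estimated correlation (1.08, adjusted p = 0.399). Exon sense-overlapping lncRNAs were not called with no filter (0.04, adjusted p = 0.0756) or the estimated correlation (0.07, 0.125), and gave 0.02 to 0.12 with 1 library left out. Natural antisense lncRNAs were called at 1 FPKM (0.47, adjusted p = 0.0157), with TMM within the table (0.20, 0.0452), filterByExpr (0.53, 0.00277) and 20 fragments (0.41, 0.0367), with 0.48 to 0.85 with 1 library left out. Intronic antisense lncRNAs were called in the same 4 settings (0.80, 0.45, 0.50 and 0.44, adjusted p from 0.0161 to 0.0452).

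Against 1 lncRNA called in edgeR's test there were 25 with no filter, 2 without sense-overlapping lncRNAs, 64 with DESeq2, 2 with limma at each pseudocount (0.1, 0.5 and 1), 4 after quantile normalisation, 2 with the robust version, and 0 with limma without a trend, edgeR's older method, entries not summed and any 1 library left out (0 to 0). The unadjusted p was under 0.05 for 473 lncRNAs. The following totals cover the named genes other than ZCCHC8, without lists and classes. Genes called in neither setting count as kept even where their sign changed. In settings other than left-out libraries, 501 higher and 564 lower values kept their side of the threshold. A further 125 and 269 lost the call, 20 and 12 gained it and 6 reversed. With 1 library left out these were 154 and 181 kept, 27 and 59 lost and 1 and 2 gained.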

Other observations

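The tests in this part chosen only after the result was seen were those on abundant genes, pathways and compartments, unspliced pre-mRNA, the position of control replicate 2 and sense-overlapping switches, while the neighbouring gene and genomic DNA tests were planned. Abundant genes outside the lists also changed in the knockouts. CCND2, which encodes cyclin D2, fell from 441 ± 59.6 to 53.2 ± 1.58 CPM (log2 fold change −3.05 ± 0.09, adjusted p = 6.04e-09, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The claudin gene CLDN2 fell from 34.8 ± 1.73 to 5.3 ± 2.6 CPM (−2.74 ± 0.24, adjusted p = 4.93e-05), the laminin gene LAMA1 from 167 ± 24.3 to 42.1 ± 1.07 CPM (−1.99 ± 0.11, adjusted p = 1.15e-06) and the growth factor gene EREG from 65.7 ± 7.49 to 16.5 ± 6.14 CPM (−1.98 ± 0.18, adjusted p = 6.37e-05). Desmocollin 2 (DSC2, 4.75 ± 5.78 to 39.3 ± 3.1 CPM, 3.2 ± 0.44), prostacyclin synthase (PTGIS, 66.3 ± 57.8 to 399 ± 10.5 CPM, 2.63 ± 0.38), filaggrin (FLG, 76.9 ± 71 to 557 ± 53.5 CPM, 2.90 ± 0.42) and the semaphorin gene SEMA5A (93.3 ± 74.7 to 554 ± 13.2 CPM, 2.60 ± 0.36) rose, with adjusted p up to 0.00106. Their control libraries lay far apart, and without control replicate 2 the values of DSC2, PTGIS, FLG and SEMA5A were 5.87, 3.97, 4.38 and 3.77. These 8 genes were called with each library left out.

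Among pathways and compartments listed in the coding table, 13 of 248 KEGG pathways (8 upward and 5 downward) and 8 of 370 Gene Ontology components (7 and 1) passed camera, and 0 did with an estimated correlation (smallest adjusted p = 0.891 and 0.999). Of 82 genes of the proteinaceous extracellular matrix, 23 rose and 5 fell (median 0.24, adjusted p = 5.39e-06), among them the WNT ligand genes WNT2B (1.48 ± 0.13) and WNT5B (1.26 ± 0.12) and the collagen crosslinking enzyme gene LOX (0.86 ± 0.09), which rose. Of 28 genes of the citrate cycle, 8 fell and 1 rose (median −0.21, adjusted p = 0.02), with falls of MDH2 (−0.61 ± 0.08), OGDH (−0.49 ± 0.08) and CS (−0.31 ± 0.06). Of 16 genes of heparan sulfate synthesis, 4 rose and 0 fell (median 0.27, adjusted p = 0.0352), including EXT1 (0.56 ± 0.07), and of 45 stress fibre genes 10 rose and 3 fell (median 0.11, adjusted p = 0.0403), including the tropomyosin genes TPM4 (0.67 ± 0.08) and TPM1 (0.42 ± 0.05). Hedgehog signalling (5 rose and 1 fell of 24, median 0.11, adjusted p = 0.0161) held the same WNT2B and WNT5B, and 5 of 15 genes of pentose and glucuronate conversion fell (median −0.21, adjusted p = 0.0161), among them the klotho gene KL (−3.86 ± 0.33).

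Bidirectional lncRNAs were higher in the knockouts, with a median of 1.08. A rise of the neighbouring coding genes was not seen and so does not account for it, with a median of −0.002 (95% interval −0.03 to 0.02) for the genes listed beside 244 of these lncRNAs. Genomic DNA in the knockout libraries would raise genes that kidney cells do not use, but 379 olfactory receptor genes had a mean rise of 0.0031 FPKM (−0.0061 to 0.014) against a median of 0.856 for the lncRNAs. More unspliced pre-mRNA would raise intron sense-overlapping lncRNAs as much, and their median lay below that of bidirectional lncRNAs (difference −0.8, interval −1.08 to −0.58). Reduced decay of these transcripts in the knockouts stays a hypothesis that was not tested, since levels alone cannot separate it from more transcription and ZCCHC8 mRNA, at 44.2 CPM against 80.1, does not show whether the protein was lost, and a difference between cultures or clones also stays open.

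Control replicate 2 lay between control replicate 1 and the knockouts. A culture state confined to matrix and TGF-beta genes would leave other genes in place, yet 950 abundant called genes outside both lists stood at a median of 18.8% of the way (95% interval 17.8% to 20%) against 19.8% in the lists. This covers only a state limited to the genes of these lists, and a broader difference between the control cultures was not tested. Knockout cells or RNA mixed into control replicate 2 would shift unrelated transcripts by 1 share, and bidirectional lncRNAs stood at 25.1% (14.3% to 34.7%), beside 20.3% and 19.6% for genes that rose and fell at least 2-fold. Mixing may be the cause, as may a part of the control culture whose cells resemble the knockouts, which would give the same values. Single abundant genes lay on both sides of that share, such as EMB (−1.1%) and TLL2 (0.7%) below it and PDE11A (40.4%) and VGF (44%) above it. Whether this spread exceeds that of a single share was not tested. The lncRNA entries of ZBTB24, DYSF and BACE2 were at 0 in control replicate 2. Zeros of exon sense-overlapping entries also switch between replicates (below), so they do not decide the question. Most coding genes with the largest rises lay below 20%, on few fragments. Control replicate 2 held 1 fragment of SAA1 (35 and 21 in knockouts) and 2 of POPDC3 (56 and 33). It held 0 of RP11-618P17.4 and CTD-3105H18.16, 1 each of SERF1B and CSGALNACT1, and 10 of MME (87 and 74). Low control values helped to rank these genes among the largest rises, so they do not decide it either. The cholesterol (2.8%), histone (−8.1%) and G2/M (−14.8%) members lay lower, with intervals that included 20%.

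Sense-overlapping lncRNA transcripts with 0 fragments in one group and many in the other were frequent among the strongest lncRNA values. If the authors' estimation moves fragments between transcripts of 1 coding gene, replicates of a group should switch too. Switches from 0 to at least 20 fragments between replicates were 12.4 times as frequent among exon sense-overlapping lncRNAs (129 of 1454 pairs, 8.87%) as among intergenic ones (14 of 1956, 0.72%). Such movement may therefore be the source of some of these values, among them those of ZBTB24, GOLGA8A and RAB15, whose coding and lncRNA entries summed to close levels in both groups. For IGFBP3, DYSF, BACE2, TENC1 and ZNF138 the sums moved with the lncRNA entry, and a change of transcript use in the knockouts was not tested.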
